A study of Solanum lycopersicum with 4 samples.

How the data were processed

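Small RNAs were measured in shoots of 14-day-old tomato seedlings of the cultivar M82, grown with 16 h of light and 8 h of dark at 24 °C. Per the labels, 2 libraries came from control plants that carry the 35S:LhG4 driver alone, and 2 libraries came from plants in which the same driver expresses an artificial miRNA against SlDCL3. The groups are called control and silenced below. Total RNA was extracted with Tri-reagent and the libraries were made with the TruSeq small RNA kit, per the labels' protocols. The trimming, filtering and any alignment of the reads are not given in the sources used here.

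The authors deposited a table per library with a row for each distinct sequence, and, per the file headers, its number of reads as a raw count and the same number as RPM, scaled to the total of the library. In each deposited file the RPM value equals the count divided by the file's total and scaled to RPM, within 0.0188% in the library where the fit was poorest. The sequences ran from 18 to 26 nt and no sequence was listed more than once within a library. Library size was therefore taken as all reads of 18 to 26 nt in the table. The plan had named reads of 18 to 30 nt, and longer reads were not analysed here. The depth was 6737281 and 7458245 reads in control replicates 1 and 2, and 4123341 and 2667030 reads in silenced replicates 1 and 2. A single read was thus worth 0.148, 0.134, 0.243 and 0.375 RPM in that order. The floor that a count of 0 allows was set at 3 reads per library, and it covers counting error only, since reads amplified by PCR are not independent molecules.

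Groups were taken from the labels, and every test compared the 2 silenced with the 2 control libraries. Each library counted as a replicate because the labels list it as a separate sample. Libraries of a group differed by more than sampling noise, with a chi-square per sequence of 2.59 between the controls over 56115 sequences and 2.56 between the silenced libraries over 16611 sequences. This speaks against a library deposited again, but not against repeated preparations of the same RNA, since reads amplified by PCR also exceed sampling noise. The series design calls the libraries biological replicates without saying how the plants were grown apart, so p-values rest on the spread between these libraries, which may be technical. In edgeR that spread is estimated with information shared over all tested sequences. Its p-values therefore do not measure the spread of a single sequence alone. Percentages of reads and of distinct sequences per length were compared with a two-sided exact permutation test over the 6 assignments of the libraries, which cannot give a p below 0.333. Distinct sequences were counted after each library was thinned at random, with a fixed seed, to the 2667030 reads of the shallowest library.

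Single sequences were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test without a replicate block, with normalization factors of 1 so that fold changes are on the RPM scale. Sequences had to pass filterByExpr with its default minimum count of 10 and total of 15, which left 46911. Calls were made at a false discovery rate of 0.05 by the Benjamini-Hochberg method, and the standard error (SE) of a log2 fold change was its absolute value divided by the square root of F. Counts for these 46911 sequences were simulated in 5 draws with 200 changed in each, and over the draws the test recovered 6.06% of 330 sequences with an absolute log2 fold change of 1, 50.7% of 335 at 2 and 91.0% of 335 at 3, with 20 false calls among 515. With 200 changed sequences the false discovery rate is reached at a smaller p than with the 41155 calls made in the real libraries, so these shares do not give the recovery of the real comparison.

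A list of 55 miRNA and tasiRNA sequences, written from memory before the data were examined, held 35 conserved miRNAs, 13 miRNAs that trigger phased siRNAs, 4 other miRNAs of the Solanaceae, 2 tasiRNAs and the anther miRNA miR2275. Names and sequences were not checked against miRBase, so a listed name may differ from the current entry, and the targets given are textbook background for the listed family. A sequence had to match a listed one exactly. Of the 39 miRNA families listed, 31 have an annotated gene in the RefSeq table of assembly SLM_r2.1, which was used for names only. Lists and length classes, 12 sets in all, were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and the lists with fry, in limma 3.58.1. The sequences named in the text were fixed by rule before the data were examined, except miR168, miR5300 and the miR156 family member TGACAGAAGAGAGTGAGCAC, which were named after their values were seen. Those under the rule are the listed sequences that pass over the list alone, at most 12 by absolute log2 fold change, the 2 most abundant members of each list, and the 4 largest falls and 4 largest rises among single sequences that pass the test, have groups that do not overlap and average at least 5 RPM.

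Alternatives were TMM factors, DESeq2 1.42.0 with its own size factors, the replicate number as a block, leaving out each library in turn, a looser filter of 5 reads over the 4 libraries, TMM factors computed from the 34 listed sequences with at least 50 reads over the 4 libraries, a denominator of 20 to 25 nt, and leaving out the 20 most abundant sequences of each library, 27 in all. The TMM factors from listed sequences were planned for the list and added for the other sequences after the data were seen. Overlap between sequences was scored as 18 shared bases on the same strand. A genome was not used here, so the planned counts per window and per gene, the comparison by gene density, the shares of organelle, ribosomal and transfer RNA, and the match of an artificial miRNA to the SlDCL3 transcript are not analysed here. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.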

Results

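Small RNA populations were profiled in seedling shoots of tomato plants in which SlDCL3 was silenced and in control plants of the driver line, with 2 libraries per group. DCL3 is the Dicer-like enzyme known to cut the 24-nt siRNAs that guide RNA-directed DNA methylation in plants. DCL4 and DCL2 are known for 21- and 22-nt siRNAs, and DCL1 for miRNAs. The control libraries held 6737281 and 7458245 reads of 18 to 26 nt in 2105846 and 2240272 distinct sequences, and the silenced libraries 4123341 and 2667030 reads in 1365088 and 1037292 distinct sequences. Between 63.3% and 77.4% of the distinct sequences of a library were seen once. SlDCL3 mRNA was not measured by these libraries, so the extent of its silencing was not analysed here.

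The first comparison asked how the length of the small RNAs differed between silenced and control shoots. Reads of 24 nt made up 48.8% ± 2.09 (SD, n = 2) of the control reads and 7.02% ± 0.625 (SD, n = 2) of the silenced reads, a difference of -41.7 percentage points. The 23-nt share was also lower in silenced shoots, at 6.73% ± 0.295 against 13.2% ± 0.438 (SD, n = 2 each). The 21-nt share was 35.0% ± 0.763 in silenced and 17.9% ± 1.14 in control shoots, and the 22-nt share was 28.6% ± 0.193 against 13.9% ± 0.551 (SD, n = 2 each). In silenced shoots 21-nt reads were thus the commonest class, whereas 24-nt reads were the commonest in both controls.

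Lengths that are rare in the controls had larger shares in the silenced libraries. The 20-nt share was 7.96% ± 0.0694 against 1.93% ± 0.253 in the controls, or 4.12-fold higher. The 19-nt share was 3.97-fold and the 18-nt share 3.35-fold higher. On the long side, 26-nt reads took 3.71% ± 0.0365 of the silenced and 0.490% ± 0.0612 of the control reads (SD, n = 2 each), a 7.56-fold difference, and 25-nt reads were 1.97-fold higher. For each of the 9 lengths the silenced libraries lay on the same side of both controls and the difference exceeded the SD of either group. The two-sided exact permutation test gave p = 0.333 for each, the smallest value that 2 libraries against 2 allow, so none can pass a threshold of 0.05.

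A share of reads must fall when another rises, so each class was also set against the reads of the listed miRNAs and tasiRNAs, which took 7.80% ± 0.631 of the control and 12.4% ± 0.734 of the silenced reads (SD, n = 2 each). There were 6.28 ± 0.776 reads of 24 nt per listed read in the controls and 0.569 ± 0.0841 in the silenced libraries (SD, n = 2 each), 11.0-fold fewer. By the same measure 23-nt reads were 3.11-fold fewer. The ratio of silenced to control was 1.23 for 21-nt, 1.30 for 22-nt, 1.24 for 25-nt, 2.48 for 18- to 20-nt and 4.78 for 26-nt reads. The choice of the listed reads as the reference assumes that they did not change as a whole. Most listed reads are themselves of 21 nt, which draws the 21-nt ratio toward 1.

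**Figure D1:**
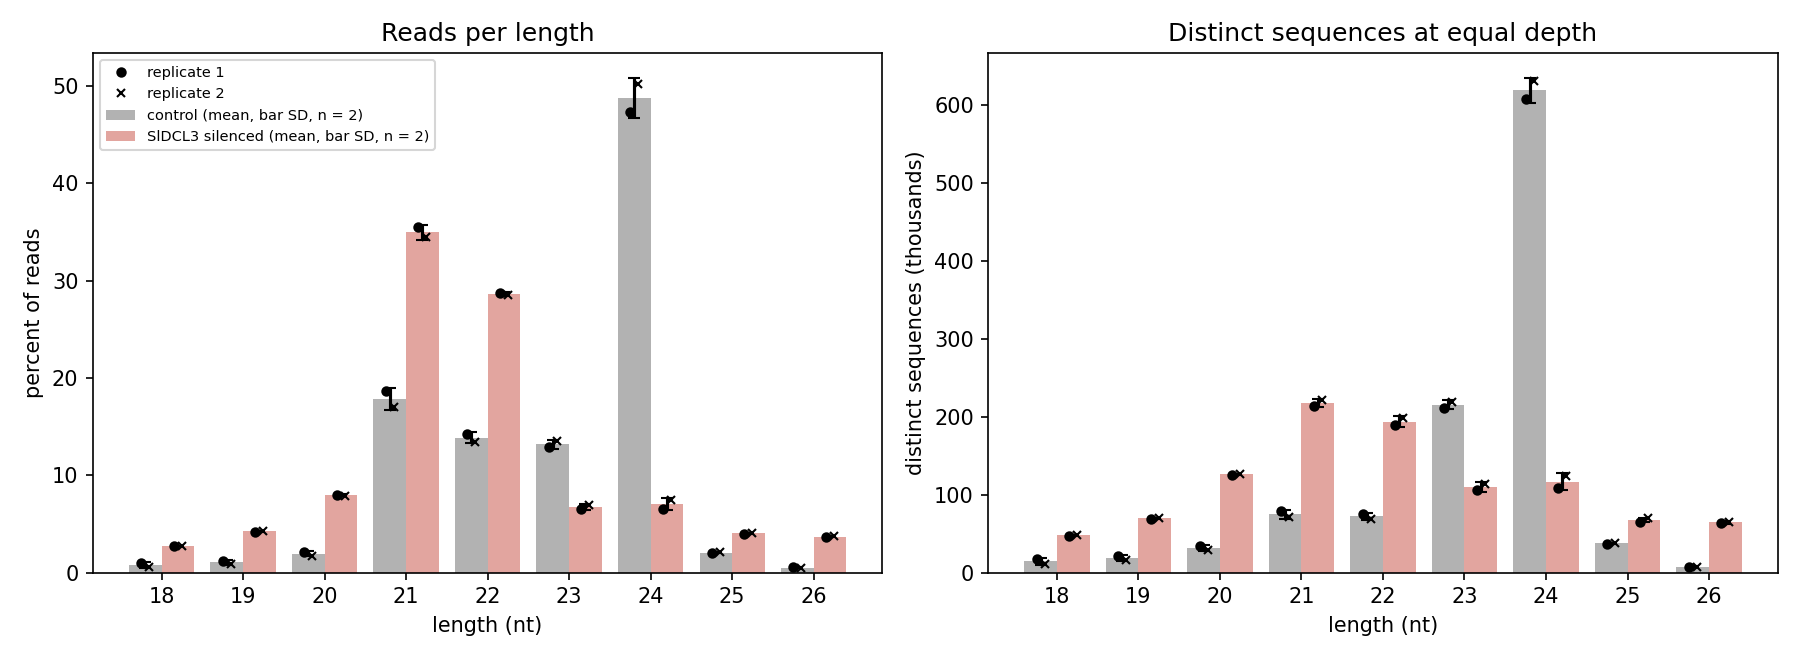
The left panel gives the percent of reads of each length from 18 to 26 nt, and the right panel the number of distinct sequences of each length after every library was thinned to 2667030 reads. Bars are means of 2 libraries with their SD, and circles and crosses mark replicates 1 and 2; at 24 nt the controls averaged 48.8% of reads and the silenced libraries 7.02%.

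The second comparison asked how many different small RNAs of each length were present, at an equal depth of 2667030 reads per library. The controls held 618482 ± 16225 distinct 24-nt sequences and the silenced libraries 116562 ± 10578 (SD, n = 2 each), 5.31-fold fewer. Equal depth holds for all reads together, so each count also follows the number of reads of its length. Each distinct 24-nt sequence was read 2.10 ± 0.0341 times in the controls and 1.61 ± 0.00411 times in the silenced libraries (SD, n = 2 each). Distinct 23-nt sequences were 1.96-fold fewer, at 109605 ± 6042 against 215076 ± 5769 (SD, n = 2 each). Distinct sequences of 21 nt numbered 217822 ± 5287 in silenced and 74710 ± 5490 in control shoots, and those of 22 nt 193670 ± 6920 against 72484 ± 4525 (SD, n = 2 each). The count was 4.00-fold higher for 20 nt, 1.80-fold higher for 25 nt and 8.80-fold higher for 26 nt. Each distinct 21-nt sequence was read 6.37 ± 0.0577 times in the controls and 4.28 ± 0.195 times in the silenced libraries (SD, n = 2 each). The groups did not overlap at any length in the number of distinct sequences, and the exact permutation p was 0.333 throughout.

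The third comparison asked which single sequences were lower or higher in silenced shoots. Of 46911 sequences tested, 24664 were lower and 16491 higher in the silenced libraries by edgeR's quasi-likelihood test. The calls were split by length. A sequence can pass the filter through a single group, so lengths commoner in a group entered mostly through it. The split by length thus partly follows from the filter. Of 22369 sequences of 24 nt, 21206 (94.8%) were lower and 164 higher. The tested sequences are few beside the 618482 distinct 24-nt sequences of the control mean at equal depth. The 23-nt class went both ways, with 3215 of 5144 lower and 1001 higher. Among 21-nt sequences 4972 of 6660 were higher and 34 lower, and among 22-nt sequences 5658 of 7145 were higher and 44 lower. At 20 nt 1818 of 2089 were higher, at 19 nt 866 of 988, at 18 nt 494 of 596, at 25 nt 768 of 1080 and at 26 nt 750 of 840. As sets, all 9 lengths passed camera at the preset correlation, but none did with an estimated one, where the adjusted p was 0.0867 for 24 nt and ran from 0.0629 to 0.369. With factors from the listed miRNAs, camera with an estimated correlation passed 19, 20, 21, 22 and 26 nt (adjusted p = 0.0242, 0.0228, 0.0157, 0.0179 and 0.0242). It did not pass 18, 23, 24 and 25 nt (adjusted p = 0.0848, 0.560, 0.0851 and 0.0757). The estimated correlation itself changed between these settings, at 21 nt from 0.0585 to 0.00184. Camera sets a length against all other tested sequences, many of them 24-nt ones that fell. A length that did not change can thus pass as higher.

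**Figure D2:**
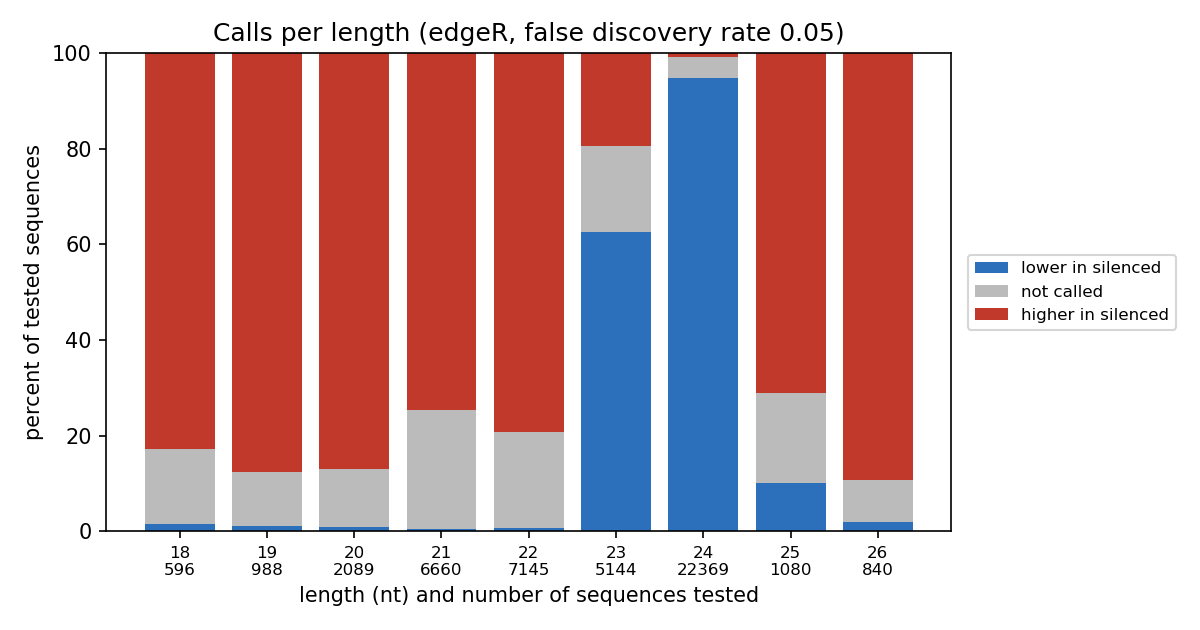
Each bar splits the tested sequences of a length, in percent, into those lower, not called and higher in silenced shoots by edgeR at a false discovery rate of 0.05, with the number tested under each length in nt. Most tested 24-nt sequences (94.8%) were lower, and 89.3% of the tested 26-nt sequences were higher. A sequence can pass the filter through a single group, so this split partly follows from the filter.

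Of the 41155 calls, 8001 had groups that did not overlap and a mean of at least 5 RPM, and the largest changes among these were named. The 4 largest falls were 24-nt sequences with 0 reads in both silenced libraries. AGTAGAACCGAAGAACTGAAGAAG averaged 88.1 ± 8.72 RPM in the controls (SD, n = 2), at least 95.1-fold more than the mean floor of 3 reads per library in the silenced libraries, 0.926 RPM. ACAATCACTTCGGGACTTGAGCCT was at 53.4 ± 3.34 RPM, TGTAAGGATATGACACATGAGCCC at 49.3 ± 12.7 RPM and ATGTAGGACTAGCTTCCACTCCCT at 35.6 ± 1.63 RPM in the controls (SD, n = 2 each), which makes them at least 57.7-, 53.3- and 38.4-fold lower in the silenced libraries. The 4 largest rises were 26-nt sequences with 0 reads in both controls. ATAACTCAACAACTCTGGACAAGAGT averaged 50.3 ± 1.51 RPM in the silenced libraries (SD, n = 2), at least 119-fold above the mean control floor of 0.424 RPM. GATGAATGAAGAACACAAGAACTTTC reached 34.6 ± 3.87 RPM, ATAGAAACTGTATAATTCGCTATACA 20.8 ± 2.86 RPM and AGTATATGTAGACCTTACCCCTGCCT 16.8 ± 2.80 RPM (SD, n = 2 each), at least 81.7-, 49.0- and 39.6-fold higher. Their places in the genome are not analysed here.

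The number of higher sequences differed between settings. DESeq2, which changes the test and the size factors together, called 23392 sequences lower and 8094 higher, so that lower calls made up 74.3% of the calls, against 59.9% in the edgeR test on the RPM scale. DESeq2 called 2512 (37.7%) of the 21-nt and 1923 (26.9%) of the 22-nt sequences higher, so most sequences of these lengths were not called. Its higher calls numbered 289 at 18 nt, 388 at 23 nt, 28 at 24 nt and 405 at 25 nt, and 20191 sequences of 24 nt were lower. With edgeR and factors from the listed miRNAs 25646 were lower and 12136 higher. Of 22-nt sequences 3594 (50.3%) and of 21-nt sequences 3674 (55.2%) were then higher, 102 and 108 were lower, and 74 sequences of 24 nt were higher. Without silenced replicate 1, 8136 of 72861 sequences tested were higher. Factors from the listed miRNAs lower every silenced value by 0.59 on the log2 scale relative to the controls, DESeq2's by 0.46 and TMM factors by 0.04.

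The fourth comparison followed the listed miRNAs and tasiRNAs, which in textbook models are cut by DCL1 and DCL4. Of the 55 listed sequences 41 were found and 34 passed the filter. In RPM, 24 of the 34 were higher in silenced shoots and 0 lower, both over all sequences tested and adjusted over the list alone. The median log2 fold change was 0.59. Factors computed from these same 34 sequences centre them, so that their median then lies near 0 by construction, and with these factors 5 were higher and 3 lower, adjusted over the list alone, and with DESeq2 2 were higher and 0 lower. At an unadjusted p under 0.05 these counts were 24 in RPM, 11 with factors from the listed miRNAs and 5 with DESeq2.

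The largest rise was that of miR398, which targets copper/zinc superoxide dismutases and accumulates when copper is short. Its listed tomato sequence TATGTTCTCAGGTCGCCCCTG (miR398sly) was at 45.5 ± 17.7 RPM in control and 484 ± 5.99 RPM in silenced shoots (SD, n = 2 each), a log2 fold change of 3.41 (SE 0.24, edgeR adjusted p = 1.12e-44). It stayed at 2.84 with factors from the listed miRNAs. TGCACTGCCTCTTCCCTGGCT (miR408sly), another miRNA of the copper response with copper proteins among its targets, rose from 8.39 ± 3.68 to 32.7 ± 0.352 RPM (SD, n = 2 each), with a log2 fold change of 1.95 (SE 0.29, edgeR adjusted p = 8.94e-11), or 1.35 with factors from the listed miRNAs. These were also the 2 that DESeq2 called over the list alone.

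Among the conserved miRNAs 14 of 22 tested were higher and 0 lower in RPM. TTGACAGAAGATAGAGAGCAC, of the miR156 family that represses SPL genes of the vegetative phase change, was at 3516 ± 763 RPM in control and 6935 ± 755 RPM in silenced shoots (SD, n = 2 each). The other listed member of this family that was tested, TGACAGAAGAGAGTGAGCAC, was not called in RPM, with a log2 fold change of -0.19 (SE 0.21) that became 0.31 without control replicate 1 and 0.02 without silenced replicate 2. miR319c, a regulator of TCP genes in leaf growth, had a log2 fold change of 0.94 (SE 0.22), miR171a, which targets GRAS genes, 0.86 (SE 0.30), and miR164, which targets NAC genes, 0.80 (SE 0.31). The most abundant members were miR166, which targets HD-ZIP III genes, with 31208 ± 2806 RPM in control and 50772 ± 2723 RPM in silenced shoots, and miR159, which targets GAMYB genes, with 28324 ± 1908 and 42814 ± 2379 RPM (SD, n = 2 each). With factors from the listed miRNAs none of these 6 was called when adjusted over the list alone, and over all sequences the rising miR156 family member was (edgeR adjusted p = 0.0303). There miR159 had a log2 fold change of 0.01 and the rising miR156 family member one of 0.40. With these factors the other miR156 family member, at -0.76, and miR168, at -0.53, were called lower over the list alone (edgeR adjusted p = 0.00350 and 0.0294) and were named after their values were seen. In RPM miR168 was not called, with a log2 fold change of 0.03 (SE 0.21). The controls differed in it, at 1220 RPM in replicate 1 and 551 RPM in replicate 2. Its log2 fold change was 0.72 without control replicate 1 and -0.43 without control replicate 2. It was -0.13 without silenced replicate 1 and 0.17 without silenced replicate 2, so its direction turned on which library was left out. As a set the conserved miRNAs passed camera at the preset correlation (adjusted p = 0.00243) but not with an estimated one (adjusted p = 0.369), and with factors from the listed miRNAs these values were 0.0438 and 0.346. Camera sets a list against the other tested sequences, and most sequences fell. The median log2 fold change over all tested was -1.69 in RPM and -2.28 with these factors. A list that did not change can thus pass as higher, and with these factors the median of the conserved list was -0.001. By fry, which tests a list on its own, the unadjusted p was 0.0405 in RPM and 0.162 with these factors.

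Of the miRNAs that trigger phased siRNAs, 8 of 10 tested were higher and 0 lower in RPM. miR482e, of the family that targets NB-LRR resistance genes, was at 2606 ± 95.2 RPM in control and 4713 ± 590 RPM in silenced shoots, and miR6027, of the same kind, at 548 ± 202 and 1379 ± 80.8 RPM (SD, n = 2 each). The log2 fold changes were 0.85 (SE 0.21) for miR482e, 1.33 (SE 0.21) for miR6027, 1.76 (SE 0.39) for miR4376 and 0.87 (SE 0.24) for miR6026. With factors from the listed miRNAs miR6027 and miR4376 were still called, at 0.76 and 1.19, and miR482e and miR6026 were not, both over all sequences and adjusted over the list alone. With these factors miR5300, named after its values were seen, was called lower, at -0.95 (edgeR adjusted p = 0.0207 over the list alone), against -0.34 (SE 0.30) and no call in RPM. The list passed camera at the preset correlation (adjusted p = 0.0340) but not with an estimated one (adjusted p = 0.286). With factors from the listed miRNAs it did not pass at the preset correlation either (adjusted p = 0.170). The limit of camera given above holds here too. By fry the unadjusted p of this list was 0.0181 in RPM and 0.109 with these factors. Both measured members of the other Solanaceae miRNAs were higher, miR6022 with a log2 fold change of 1.80 (SE 0.54) and miR1919 with 1.40 (SE 0.25), and with factors from the listed miRNAs both were called over all sequences but only miR1919 when adjusted over the list alone. This list did not pass camera (adjusted p = 0.106 preset and 0.369 with an estimated correlation). By fry its unadjusted p was 0.0120 in RPM and 0.0297 with factors from the listed miRNAs, over 2 members.

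The tasiRNAs that target AUXIN RESPONSE FACTOR genes were too rare for the main test. TTCTTGACCTTGTAAGACCCC was at 1.41 ± 0.101 RPM in control and 1.73 ± 0.733 RPM in silenced shoots, and TTCTTGACCTTGTAAGACCTT at 0.996 ± 0.271 and 1.41 ± 0.405 RPM (SD, n = 2 each), differences that were not detectable at 3 to 10 reads per library. The anther miRNA miR2275 had 0 reads in all 4 libraries, which allows up to 0.402 to 1.12 RPM. The call of miR164 ended without control replicate 2 (log2 fold change 0.61) or without silenced replicate 2 (0.65), and that of miR171a without control replicate 1 (0.74) or without silenced replicate 1 (0.64). Over the whole list 14 sequences were changed without control replicate 2, against 24 with all libraries.

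**Figure D3:**
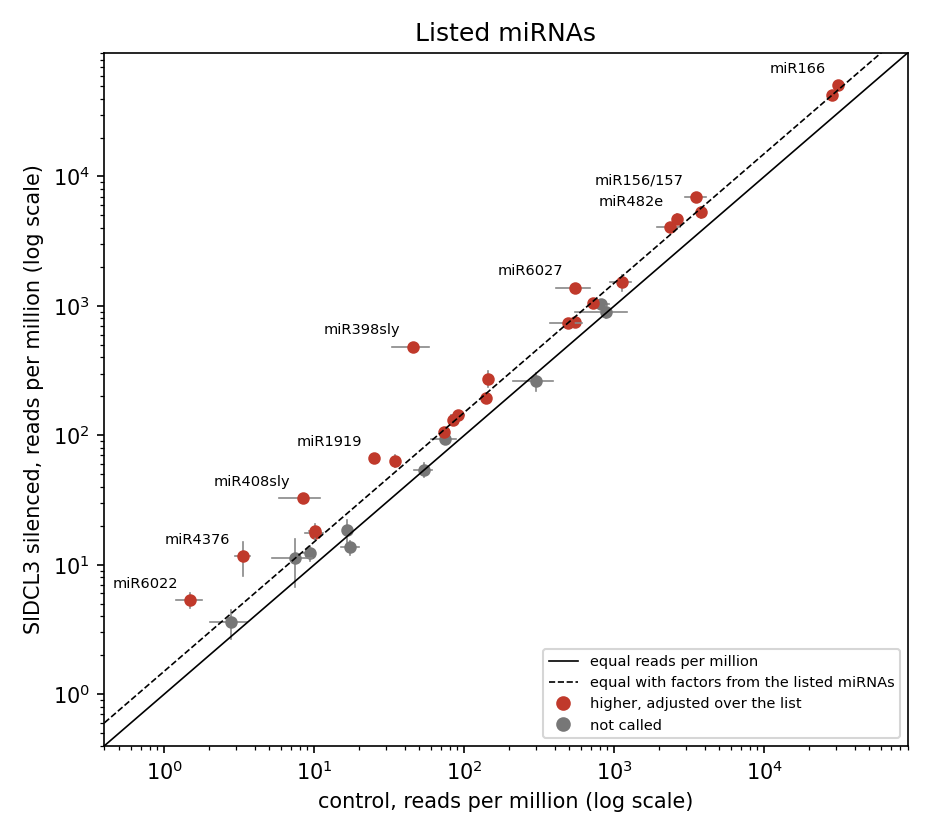
Each point is a listed miRNA among the 34 tested, with its mean RPM in control shoots on the horizontal and in silenced shoots on the vertical log axis, and thin lines span the 2 libraries of each group. Points above the solid line had more RPM in silenced shoots, and the dashed line lies 0.59 higher on the log2 scale, the shift of factors computed from these miRNAs; miR398sly lies farthest above it.

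Silenced plants were made to express an artificial miRNA against SlDCL3, so sequences specific to these plants were sought. The criteria were at least 100 reads in both silenced libraries and at most 3 in each control. None of the sequences of 20 to 22 nt met them (0 sequences), and 1 sequence of any length did, the 26-nt ATAACTCAACAACTCTGGACAAGAGT with 203 and 137 reads. In the mirror comparison 348 sequences had at least 100 reads in both controls and at most 3 in each silenced library, and 297 of these were of 24 nt and 48 of 23 nt. Both comparisons used raw reads, and a read was worth 0.148 and 0.134 RPM in the controls but 0.243 and 0.375 RPM in the silenced libraries. The criteria were therefore easier to meet in the mirror comparison, so 348 and 1 cannot be compared directly. The artificial miRNA was thus not seen as an abundant sequence specific to the silenced libraries, and whether a rarer sequence matches the SlDCL3 transcript is not analysed here.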

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

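Factors from the listed miRNAs for single sequences and the shared ends without abundant sequences were chosen after seeing the data; the other alternatives were planned. Of 355 values, 291 were scored the same. This meant within 1 SD for shares and shared ends, and within a fixed fold for counts. For single sequences it meant that sign and call status were kept. Another 27 moved past these bounds without a change of sign. There were 27 single-miRNA calls that ended over the list alone (5 of these still passed over all sequences), and 3 that were gained. A further 7 values changed sign, and among them miR168 with factors from the listed miRNAs also became a call. For shares per length, the replicate block and each left-out library stay within 1 SD by arithmetic, so many of the 291 were fixed in advance. The changes of sign were in miR168 and a miR156 family member, neither of them called in RPM. The log2 fold change of miR168, 0.03 in RPM, was -0.0084 with TMM factors, -0.53 with factors from the listed miRNAs, -0.40 with DESeq2 and -0.43 to 0.72 without each library in turn, and that of the miR156 family member, -0.19 in RPM, was -0.56 to 0.31 without each library in turn. Without each library in turn the 24-nt difference in reads was -43.2 to -40.3 points; with 2 libraries per group such a move is below 1 SD by arithmetic and says nothing about stability. With 20 to 25 nt as the denominator the difference in the share of reads (silenced minus control) was 6.93 points for 20 nt, 20.9 for 21, 17.8 for 22, -5.96 for 23 and 2.42 for 25 nt, and in the share of distinct sequences 12.2, 19.1, 16.4, -7.31 and 4.55 points for the same lengths. Without the 20 most abundant sequences it was 2.78 for 18 nt, 4.58 for 19, 8.51 for 20, 16.7 for 22, -6.97 for 23, -50.8 for 24, 3.13 for 25 and 4.56 for 26 nt. Both settings make the denominator smaller, which by itself rescales every share. Leaving out abundant sequences also takes reads out of their own lengths.

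Lower sequences numbered 18191 to 34943 and higher ones 8136 to 13283 without each library in turn, where a lone library is assumed to vary like the other group. The looser filter tested 432777 sequences, against 46911 in the main test, so more could be called. It called 57227 lower and 37618 higher. DESeq2 called 8094 higher. The cause of the differences with DESeq2 and without a library was not tested. Listed sequences changed, adjusted over the list alone, numbered 15 with TMM factors, 8 with factors from the listed miRNAs, 2 with DESeq2, 15 with every found member tested among themselves, and 14 to 24 without each library in turn. With the replicate number as a block 23852 sequences were lower, 14534 higher and 25 listed ones changed. Deviations of like-numbered libraries correlated at 0.00383 over 24764 sequences. Many sequences were much rarer in a group than in the other, where a deviation is mostly counting noise. This value therefore cannot exclude that the numbers pair the samples. The 8 named single sequences kept their calls in all 72 values. They were chosen as the largest changes, each with 0 reads in a whole group, so this says little about stability. Not run without a genome were perfect matches to the genome, windows and their size, genes, multiple matches and gene density. Depth limits the silenced libraries most, where a read is worth up to 0.375 RPM.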

Other observations

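The tests of closure for reads per length, of size selection, of the preference for 3' ends, of the ends without abundant sequences and of shared 24-nt sequences, and of 5' bases other than A at 26 nt, were chosen after the result was seen. The bases at the 5' ends differed between silenced and control shoots. Among 26-nt reads, 85.2% ± 0.291 began with A or G in the silenced libraries and 64.3% ± 1.66 in the controls (SD, n = 2 each). The same share was 87.3% ± 0.482 against 71.4% ± 0.664 at 25 nt, 84.5% ± 0.589 against 77.1% ± 0.190 at 24 nt and 74.9% ± 0.488 against 51.7% ± 0.234 at 23 nt (SD, n = 2 each). At 18 to 20 nt the share was lower in silenced shoots, with 48.6% ± 0.230 against 52.2% ± 0.380 at 20 nt (SD, n = 2 each). At 21 nt it was higher, with 31.8% ± 1.32 against 17.6% ± 0.0657 of reads and 61.3% ± 0.594 against 51.3% ± 0.298 of distinct sequences at equal depth (SD, n = 2 each). At 22 nt it was lower over reads, with 61.9% ± 0.140 against 69.0% ± 0.492, but not over distinct sequences, with 47.8% ± 0.0167 against 47.1% ± 0.162 (SD, n = 2 each). Over distinct sequences the 23-nt share was 74.4% ± 0.0972 against 50.9% ± 0.194 and the 26-nt share 84.9% ± 0.193 against 63.7% ± 2.61 (SD, n = 2 each), so a few abundant sequences do not set the 23- and 26-nt values. A and G did not change alike. At 24 nt 64.5% ± 1.30 of silenced against 67.8% ± 0.114 of control reads began with A. For G the values were 19.96% ± 0.706 against 9.31% ± 0.0754. Over distinct 24-nt sequences A was higher, at 63.76% ± 0.801 against 60.99% ± 0.0915. At 26 nt A took 52.6% ± 0.751 against 28.5% ± 0.267 of reads. G took 32.5% ± 1.04 against 35.7% ± 1.93 of reads, and 30.12% ± 0.682 against 30.07% ± 2.98 of distinct sequences (SD, n = 2 each). The exact permutation test cannot go below p = 0.333 for any of these shares.

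At equal depth, between 38.4% and 39.9% of the distinct 24-nt sequences of a silenced library also occurred in a given control, and 17.9% to 20.4% in the other silenced library. Between 28.7% and 29.8% of those of a control occurred in the other control, and 6.91% to 7.84% in a given silenced library. The silenced sets are smaller, which lowers the chance of a match with them.

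The lower 24-nt share in silenced shoots was set against technical explanations. Closure, the forced fall of a share when others rise, is argued against by 24-nt reads per listed read, which were 11.0-fold fewer. Loss of long inserts in size selection is argued against by the 7.56-fold higher 26-nt share. The lower depth of the silenced libraries was tested with distinct 24-nt sequences, which were 5.31-fold fewer at equal depth. Thinning equalised all reads and not those of 24 nt, so this count had to fall with the 24-nt share. It therefore cannot judge depth, which by itself does not shift a share of reads. What the design names, silencing of SlDCL3, remains as a hypothesis.

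For the higher shares of 18- to 20- and 26-nt reads, closure alone is argued against, since 18- to 20-nt reads per listed read were 2.48-fold and 26-nt reads 4.78-fold higher. Random breakdown of RNA could not be judged from duplex partners with 2-nt overhangs, whose ratio to other overhangs was 1.10 at 20 nt and 0.611 and 0.521 at 26 nt in silenced libraries, because control 24-nt sequences showed no peak either. For the short reads that share sequence with 24-nt sequences called lower, silenced reads at the shared 3' end were 6.17 times those per internal position. The controls passed the bound of 2 as well, at 3.85. These values argue against evenly placed breaks in such reads of both groups, but do not tell why they rose. At 26 nt breakdown was predicted not to raise the share of reads with A at the 5' end. That share was 52.6% ± 0.751 in silenced against 28.5% ± 0.267 in control shoots (SD, n = 2 each). The outcome set against breakdown was an overhang ratio of at least 2 in both silenced libraries, which was not met. Breakdown at 26 nt therefore could not be judged by the bounds set, although this part of its prediction failed. Whether the rise may come from short reads that share 3' ends with the lost 24-nt siRNAs could not be judged. Reads that share 18 bases with a 24-nt sequence called lower, whatever their ends, were the smaller part of these classes. They made up 15.3% ± 0.0240 of silenced reads at 18 nt, 18.6% ± 0.0848 at 19 nt and 19.3% ± 0.0284 at 20 nt. By the same overlap these sequences cover 41.0% ± 0.414 of the control 24-nt reads (SD, n = 2 each), so the part of the other 24-nt sequences is not known. Reads of 18 to 20 nt at a shared 3' end were 5.44-fold higher, at 8761 ± 66.7 against 1610 ± 280 RPM (SD, n = 2 each). The bound of 2-fold, however, was already met by all reads of 18, 19 and 20 nt (3.35-, 3.97- and 4.12-fold). The controls also already had fewer reads at shared 5' ends, at 681 ± 130 RPM (SD, n = 2). Reads at 5' ends were 2.85-fold and at internal positions 3.40-fold higher, or 3.57- and 5.21-fold against 5.74-fold at 3' ends without 24-nt sequences related to abundant or listed ones, and the controls preferred 3' ends over internal positions too, at 3.85, so whether the rise is particular to 3' ends stays open.

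A candidate explanation for the 21- and 22-nt sequences called higher is that other enzymes cut the precursors of 24-nt siRNAs. Of the 10630 called higher, 3924 (36.9%) shared 18 bases with a 24-nt sequence called lower, against 471 of 3097 (15.2%) not called, a ratio of 2.43. The few called lower shared it as well, in 33 of 78 (42.3%), so the overlap is no mark of the rise alone, and most of the higher calls shared no such stretch with a 24-nt sequence called lower. Closure was tested with factors from the listed miRNAs, under which 7268 calls (68.4%) stayed, between the bounds set for either answer, so its part in the other 3362 calls cannot be told apart from a smaller rise. At 26 nt the overlap was seen for 500 of 750 sequences called higher (66.7%), 3 of 73 not called (4.11%) and 8 of 17 called lower (47.1%).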
